A study of Homo sapiens with 24 samples.

How the data were processed

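RNA was measured in 24 libraries of BXPC3, MIAPACA2 and PSN1, with 4 vehicle and 4 AM-9747 libraries per line taken at day 6. The labels give the genotype as WT beside the description of the lines as MTAP-deleted. Per the labels and the submitters' notes, RNA was extracted with a column kit and made into stranded poly(A) libraries with the NEBNext Ultra II Directional kit. Per the submitters' processing notes, reads were trimmed with fastp 0.19.8 and aligned to GRCh38 with HISAT2 2.2.0, and the authors worked in R 4.0.2 with DESeq2 1.34.0. The read counter and the annotation release are not given in the sources used here. The deposited table holds raw read counts per gene, 60366 entries by 24 columns, and each column was matched to a sample by its label, with 0 columns left over.

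Of the entries, 56271 were matched by stable ID to GENCODE 29, which gave names, biotypes and coordinates. The 1862 entries without an Ensembl ID are miRNA precursors, with 0.000627 to 0.0254% of the counts of a library. Total counts ran from 22.4 to 45.6 M, so a gene at 1 CPM had 22.4 counts or more in each library before scaling, and a gene with 0 counts could still have up to 3 at 95% confidence. For genes with such a group no fold change is printed.

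The main test was a joint fit of the 6 groups by edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr by group) in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). A prior count of 2 was used only for log2 CPM values, as in the correlations between libraries, and was not set in the fit. The joint fit tested 22883 genes with 18 residual degrees of freedom (median prior 5.91). Each p-value was adjusted by Benjamini-Hochberg within its comparison, and adjusted p below 0.05 counts as passing. The comparisons were AM-9747 against vehicle in each line, the mean of the 3 responses, and the difference of the responses between lines, jointly (an F test) and by pair. Levels are CPM with TMM scaling. Genes called the same way in all lines pass in each line with the same sign. The count for independent lines is the number of genes tested times the product of the shares called. The lines share no control.

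38 gene lists, written from general knowledge before the data were examined, were tested with camera at a preset correlation of 0.01, with at least 5 measured members and adjustment over the lists in a line. The lists were repeated with an estimated correlation and with fry. Camera sets the members of a list against the other genes. Fry tests only whether the members changed, so it can call lists where many genes of a line changed. The counts over the list alone adjust p within the list's members. Where a member had no count in a group, list medians set that group to a bound of 3 counts, and members with at most 3 counts in both groups were left out.

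Genes are named by a rule fixed in advance: 8 key genes; in each line the 8 largest rises and 8 largest falls among protein-coding genes with adjusted p below 0.05, a mean of at least 5 CPM over the 8 libraries and no overlap of the groups; the 10 rises and 10 falls shared by the lines that met these filters in each line, by the largest smallest change; the 6 largest opposite responses with a mean of at least 5 CPM over the 2 lines; and 3 members per list by the change of the mean response. Of the last, the text prints those that bear on a comparison. Other names were chosen after their values were seen.

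The procedure was tested on simulated data: negative binomial counts drawn with each gene's mean and dispersion in its line and the real library sizes, in which 200 genes were changed 1.5-fold, 2-fold or 4-fold in the treated libraries of all lines. The joint fit gave a false share of 3.08% in BXPC3 (2 of 65 calls), 7.81% in MIAPACA2 (5 of 64), 71% in PSN1 (191 of 269) and 16% for the mean (23 of 144). A false share depends on how many genes are truly changed, so the simulated shares need not hold for the real calls. It found 75.8%, 69.7% and 77.3% of 4-fold changes and 19.4%, 17.9% and 34.3% of 2-fold changes in BXPC3, MIAPACA2 and PSN1. A fit of each line alone gave false shares of 7.61%, 6.38% and 2.78% and found 51.5% of 4-fold changes in PSN1. DESeq2 gave 85% and voom 17.8% in PSN1. The lines differ in spread, with a biological coefficient of variation of 26.6%, 32.1% and 55.1%. PSN1 calls of named genes and lists are printed with the separate fit where it tested them. Of the 200 genes, 19 rises and 29 falls were found in all lines. In a second simulation genes were changed 1.5-fold, 2-fold or 4-fold in treated PSN1 libraries alone, among them a list of 65 genes raised 1.5-fold. The raised list was called in PSN1, and 1 other list was called with it. Genes were drawn independently there, while members of the real lists correlated (estimated at 0.242 for the mitosis list in PSN1). The simulation thus does not show how often list calls are false in these data.

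Alternatives fixed in advance were DESeq2 1.42.0, median-of-ratios scaling, no scaling, no filter, a filter of at least 5 CPM, separate fits, a replicate block, adjusted p below 0.01, a test against a 1.2-fold change, CPM of the library totals, leaving out each library, and the list tests above. Chosen after the data were seen were voom with a weight per library, the mitochondrial share as a covariate with its own slope in each line, and leaving out PSN1 vehicle replicate 3 and BXPC3 vehicle replicate 4 together. Relabelled groupings of the libraries were fitted as well. No library was left out of the main results. The members that passed in the recombination list in MIAPACA2 are not reported here. Splicing was not examined, since the table holds gene counts.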

Results

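The data are gene counts from poly(A) RNA sequencing of BXPC3, MIAPACA2 and PSN1, 3 established human pancreatic cancer cell lines that the submitters describe as MTAP-deleted. MTAP clears methylthioadenosine, and its gene lies beside the tumour suppressor CDKN2A on chromosome 9. AM-9747 is an inhibitor of PRMT5, an arginine methyltransferase that modifies spliceosomal and histone proteins, and it acts together with methylthioadenosine. Each line was given AM-9747 or DMSO vehicle for 6 days, at 100 nM in BXPC3 and PSN1 and at 150 nM in MIAPACA2, so dose and line cannot be told apart for MIAPACA2. There were 4 libraries in each of the 6 groups, 24 in all. Total counts ran from 22.4 to 45.6 M (1e6) per library. The mean ± SD was 40.6 ± 3.79 M in BXPC3 vehicle, 36.5 ± 2.23 in BXPC3 AM-9747, 35.3 ± 5.21 in MIAPACA2 vehicle, 34.8 ± 3.68 in MIAPACA2 AM-9747, 30.7 ± 6.73 in PSN1 vehicle and 32.8 ± 3.73 in PSN1 AM-9747. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples. Levels are CPM (counts per 1e6 counts) as mean ± SD of 4 libraries, fold changes are AM-9747 over vehicle, log2 fold changes carry their SE, and adjusted p is the Benjamini-Hochberg value of edgeR's quasi-likelihood test unless another test is named.

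Mitochondrial transcripts took a different share of the counts in each line. They made up 7.26 ± 1.15% of BXPC3 vehicle and 7.34 ± 2.6% of BXPC3 AM-9747 counts, and 13.6 ± 6.31% and 13.6 ± 4.29% in MIAPACA2. In PSN1 they made up 33.1 ± 11.3% of vehicle counts (17.4 to 43.8%) and 20 ± 10.8% of AM-9747 counts (7.98 to 31.1%). PSN1 vehicle libraries detected 16646 to 24738 genes and PSN1 AM-9747 libraries 22386 to 27120. Each PSN1 vehicle library correlated with the others of its group at a mean r of 0.8637 to 0.911 across genes, against 0.9396 to 0.9482 in PSN1 AM-9747, 0.9674 to 0.9801 in BXPC3 and 0.9613 to 0.9721 in MIAPACA2. The biological coefficient of variation was 26.6% in BXPC3, 32.1% in MIAPACA2 and 55.1% in PSN1, and 46.4% in the joint fit of all lines. No replicate pair agreed within sampling noise (the lowest chi-square per gene was 7.165).

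**Figure D1:**
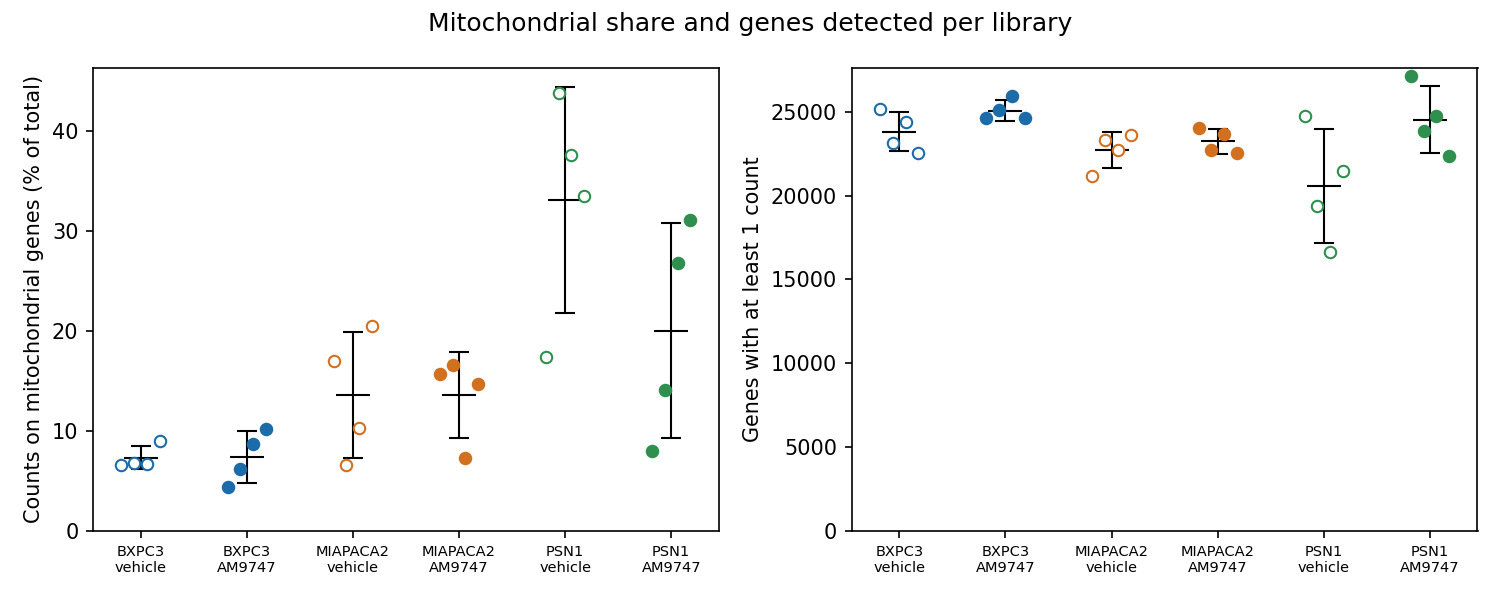
Share of counts on mitochondrial genes (left, % of total) and genes with at least 1 count (right) in each of the 24 libraries. Open points are vehicle, filled points AM-9747, and bars are the mean ± SD of 4 libraries. PSN1 vehicle libraries reach 43.8% mitochondrial counts and go down to 16646 genes.

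The first comparison asked whether AM-9747 changed the level of its target, of the target's partner and of genes tied to the MTAP deletion. PRMT5 (ENSG00000100462, GRCh38 chromosome 14, 22920511 to 22929585, minus strand) stood at 109 ± 6.83 CPM in BXPC3 vehicle and 136 ± 21.3 with AM-9747 (adjusted p 0.472), and at 47.5 ± 15.5 and 44.6 ± 11.7 in MIAPACA2 (adjusted p 0.932). In PSN1 it rose from 48.7 ± 10.4 to 96.9 ± 27 CPM (log2 0.99 ± 0.23, adjusted p 0.00332, and 0.0336 when PSN1 was fitted on its own). The difference of its response between the lines did not pass (adjusted p 0.0676). WDR77 (ENSG00000116455, chromosome 1, 111439890 to 111449376, minus strand), the partner that PRMT5 needs for activity, fell in BXPC3 from 83.6 ± 15.7 to 54.3 ± 5.34 CPM (log2 -0.62 ± 0.17, adjusted p 0.0162). That call was lost without BXPC3 AM-9747 replicate 1 (log2 -0.56, adjusted p 0.0601) or BXPC3 vehicle replicate 4 (log2 -0.48, adjusted p 0.0748). WDR77 was at 36 ± 3.70 and 27.1 ± 3.88 CPM in MIAPACA2 and at 55.1 ± 10.2 and 44.1 ± 4.45 in PSN1, with adjusted p 0.183 and 0.162.

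MTAP (ENSG00000099810, chromosome 9, 21802543 to 21937651, plus strand) was low in all groups, at 0.276 ± 0.124 and 0.858 ± 0.504 CPM in BXPC3, 0.674 ± 0.466 and 1.13 ± 0.471 in MIAPACA2 and 2.68 ± 1.98 and 1.60 ± 0.575 in PSN1. Its adjusted p was 0.104, 0.597 and 0.386, and 0.0374 with BXPC3 fitted alone. CDKN2A (ENSG00000147889, chromosome 9, 21967753 to 21995301, minus strand) had 0 counts in each BXPC3 and MIAPACA2 library, where up to 3 counts cannot be excluded, and at most 18 counts in a PSN1 vehicle and 6 in a PSN1 AM-9747 library. It was below the filter and was not tested. MAT2A (ENSG00000168906, chromosome 2, 85539165 to 85545280, plus strand), which makes S-adenosylmethionine, fell over the mean of the 3 lines (log2 -0.87 ± 0.21, adjusted p 0.00427). Its level went from 243 ± 22.4 to 126 ± 15.1 CPM in BXPC3, from 464 ± 89.9 to 206 ± 62.1 in MIAPACA2 and from 244 ± 183 to 173 ± 98.2 in PSN1. It passed in no line in the joint fit (adjusted p 0.117, 0.0710 and 0.340). Fitted alone, the adjusted p was 5.51e-04 in BXPC3, 0.00636 in MIAPACA2 and 0.520 in PSN1.

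MDM4 (ENSG00000198625, chromosome 1, 204516379 to 204558120, plus strand), an inhibitor of p53 whose splicing depends on PRMT5, fell in PSN1 from 70.7 ± 5.18 to 35.1 ± 1.30 CPM (log2 -1.01 ± 0.15, adjusted p 5.68e-05, and 0.00813 fitted alone). It stood at 17.9 ± 1.76 and 22.4 ± 1.71 CPM in BXPC3 (adjusted p 0.204) and 42 ± 9.83 and 39.9 ± 4.04 in MIAPACA2 (adjusted p 0.907). The response differed between the lines (adjusted p 8.05e-04). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434, plus strand), a driver of growth, fell in MIAPACA2 from 142 ± 27.5 to 81.7 ± 21.5 CPM (log2 -0.80 ± 0.21, adjusted p 0.0278). Without scaling of the library totals that call was lost (log2 -0.62, adjusted p 0.17). It was also lost without MIAPACA2 AM-9747 replicate 1, 2 or 4 or vehicle replicate 2 or 3 (adjusted p up to 0.12), though the log2 values stayed at -0.77 to -0.70. With MIAPACA2 fitted alone the adjusted p was 0.0249. MYC was at 182 ± 12.1 and 165 ± 17 CPM in BXPC3 and at 356 ± 56.1 and 325 ± 109 in PSN1 (adjusted p 0.776 and 0.698). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339, plus strand), which encodes the p53 target p21, passed in no line (adjusted p 0.780, 0.848 and 0.537). It was at 115 ± 4.61 and 129.8 ± 21.2 CPM in BXPC3, 3.68 ± 0.715 and 3.26 ± 0.946 in MIAPACA2 and 10.4 ± 4.82 and 12.4 ± 4.01 in PSN1.

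**Figure D2:**
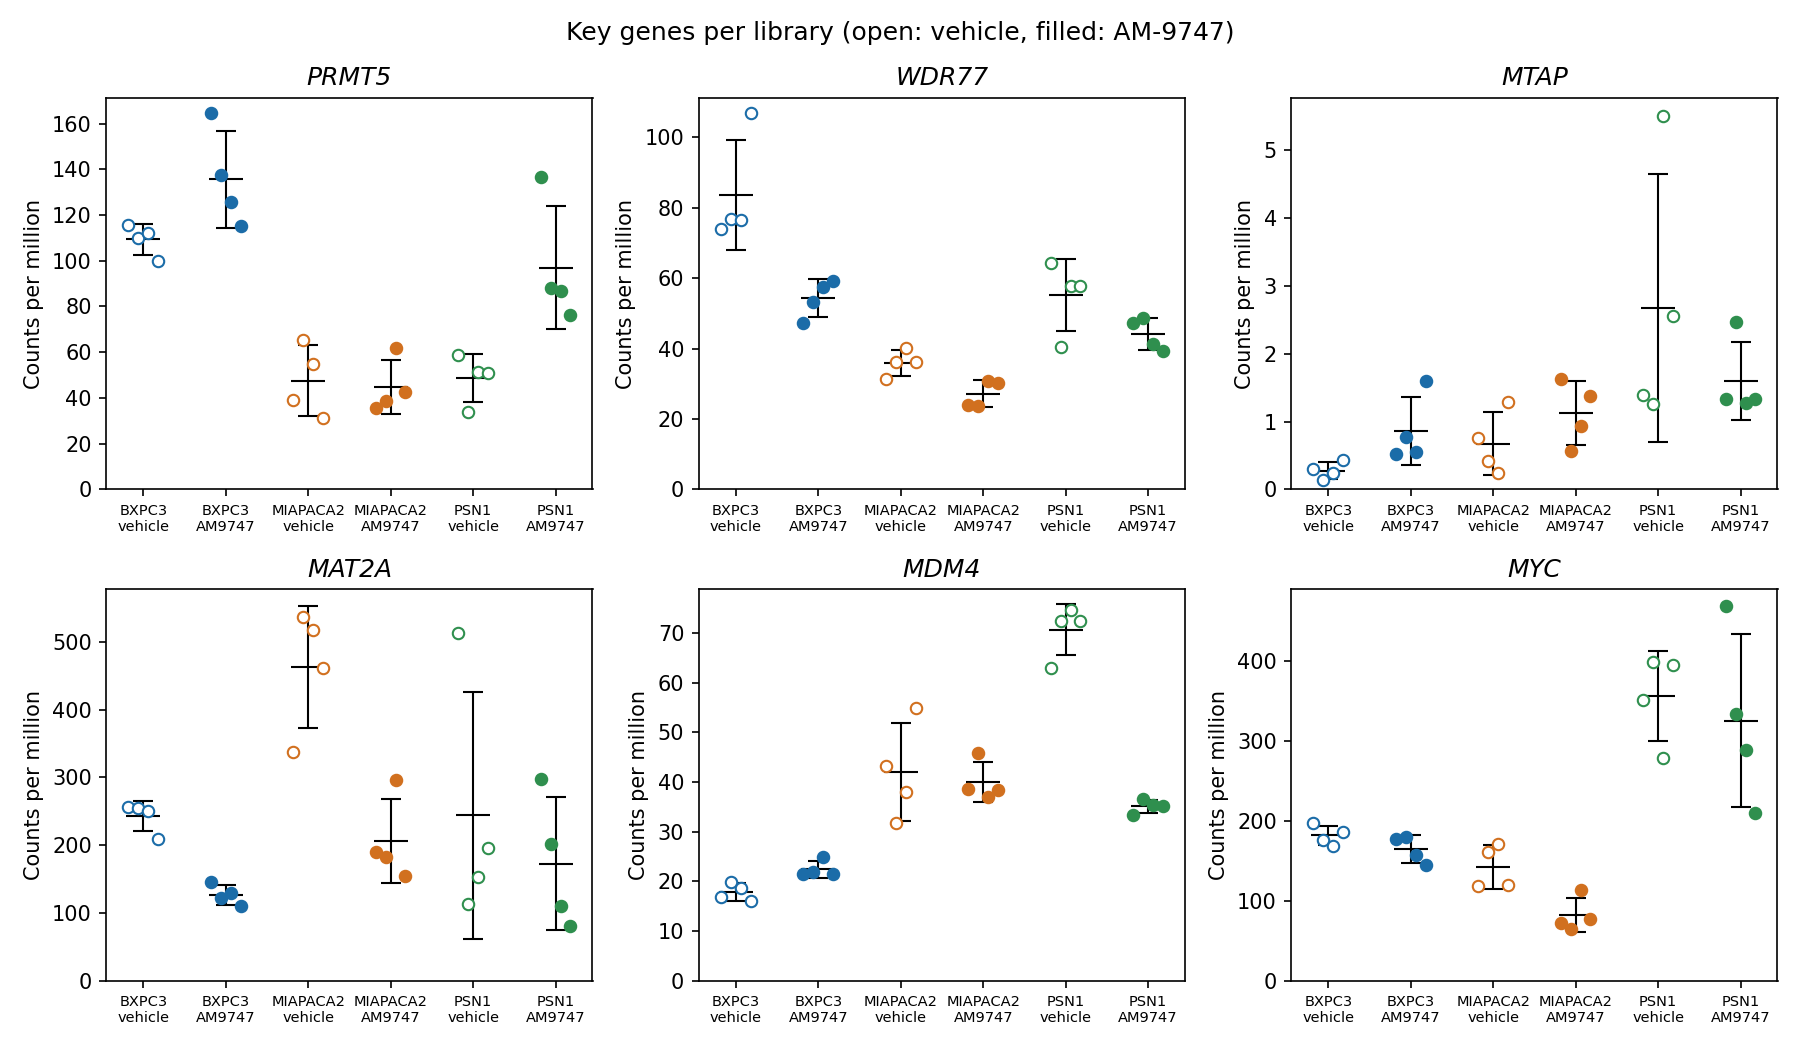
Level of PRMT5, WDR77, MTAP, MAT2A, MDM4 and MYC in each library, in CPM. Open points are vehicle, filled points AM-9747, and bars are the mean ± SD of 4 libraries. PRMT5 was higher and MDM4 lower in treated PSN1 cells.

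In BXPC3, the question was which genes responded to 6 days at 100 nM. CCL21, a chemokine that draws lymphocytes and dendritic cells, rose from 1.91 ± 0.319 to 44.8 ± 11.8 CPM (log2 4.55 ± 0.47, adjusted p 1.53e-05). The cystatin gene CST1, whose paralogs share reads, rose 8.70-fold, CGA, the common subunit of the glycoprotein hormones, 7.54-fold, and the alarmin cytokine IL33 7.21-fold. NNMT, which uses S-adenosylmethionine to methylate nicotinamide, rose from 2.66 ± 0.220 to 19.3 ± 1.57 CPM, and the transporter SLCO4A1 from 3.27 ± 0.399 to 17.5 ± 0.805 CPM. MSLN, the surface protein mesothelin, fell from 216 ± 51.4 to 24.5 ± 4.10 CPM (log2 -3.14 ± 0.49, adjusted p 1.15e-04). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell from 94.2 ± 10.9 to 11 ± 2.59 CPM, and GAA, the lysosomal acid alpha-glucosidase, from 20.2 ± 1.21 to 2.56 ± 0.432 CPM. The epoxide hydrolase EPHX2 (log2 -3.40 ± 0.34), LYPD2 (log2 -3.88 ± 0.50), SLC7A4 (log2 -3.07 ± 0.63), MMAB (log2 -2.92 ± 0.26) and PIGP (log2 -2.82 ± 0.29) also fell. Of 22883 genes tested, 2405 passed, 1014 higher and 1391 lower, with 610 and 873 of these changed at least 2-fold. Fitted alone, BXPC3 gave 5134 of 17638 genes, 2319 higher and 2815 lower. With voom the split turned, to 4892 higher and 4768 lower. The rises of IL16 (1.17 to 11 CPM, adjusted p 0.0233) and ZPLD1 (1.45 to 10.1 CPM, adjusted p 0.0387) passed in a fit of BXPC3 alone (adjusted p 1.44e-04 and 3.11e-04), and both calls of the joint fit were lost without single libraries. IL16 lost its call without BXPC3 AM-9747 replicate 3 or 4 or vehicle replicate 1, 3 or 4, with log2 2.96 to 3.25 and adjusted p up to 0.0799. ZPLD1 lost it without any 1 of the 8 libraries, with log2 2.48 to 2.97 and adjusted p up to 0.115.

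In gene lists fixed in advance, BXPC3 had 10 of 38 called by camera at its preset correlation, 0 with an estimated correlation and 11 by fry. With BXPC3 fitted alone camera also called 10, where the Sm and recombination lists were lost and the other lists below were kept. Members outside the naming rule were chosen after their values were seen. Of 29 integrated stress response genes, 9 fell and 1 rose (1 rose and 12 fell over the list alone), with a median log2 fold change of -0.48 (camera adjusted p 4.04e-09, and adjusted p = 0.167 with an estimated correlation). PSAT1, of serine synthesis, fell from 164 ± 21.8 to 34.3 ± 0.835 CPM and CHAC1, which degrades glutathione, from 35.7 ± 5.84 to 11.8 ± 0.457 CPM, while the transcription factor ATF3 rose from 25 ± 3.72 to 48.4 ± 2.90 CPM. Of 50 replication and G1/S genes, 11 fell, among them CDC45 (log2 -1.12) and POLA2 (log2 -1.63), and 2, CCNE1 and ORC6, rose (3 rose and 14 fell over the list alone; camera adjusted p 2.60e-04, and adjusted p = 0.566 with an estimated correlation). Fitted alone, 4 replication genes rose and 23 fell (camera 3.84e-04, and 0.0811 with an estimated correlation). Of 65 mitosis genes, 5 rose, AURKA, KIF14, NUF2, PTTG1 and TTK (5 rose and 0 fell over the list alone; camera 0.00739, adjusted p = 0.686 with an estimated correlation, and 0.141 with fry). In the separate fit 27 mitosis genes rose and 4 fell (camera 0.00131, fry 0.00349, and 0.37 with an estimated correlation). Splicing factors and hnRNPs held 12 genes that rose out of 46, such as RBM39 (311 to 770.5 CPM) and PRPF3 (35.2 to 88), and none that fell (14 rose and 1 fell over the list alone, camera 4.88e-05, adjusted p = 0.266 with an estimated correlation). Of the 27 Sm and snRNP proteins none passed alone, while the list stood higher at a median of 0.32 (camera 0.0277, adjusted p = 0.686 with an estimated correlation). That call was lost with fry, in the separate fit and without any of 4 single libraries (adjusted p up to 0.133).

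Mesenchymal genes leaned higher in BXPC3. The matrix genes SPARC (0.940 to 3.61 CPM) and COL4A1, the filament VIM and the repressors SNAI1 and ZEB1 rose, while COL5A1 fell, out of 28 measured (10 rose and 1 fell over the list alone, camera 0.00739, adjusted p = 0.266 with an estimated correlation). The replication-dependent histones H1-2 and H2BC5 rose out of 28, as far as poly(A) libraries hold these transcripts (2 rose and 0 fell over the list alone, camera 0.0215, adjusted p = 0.266 with an estimated correlation). Of 43 interferon response genes 6 fell and none rose (2 rose and 9 fell over the list alone, camera 0.00739, adjusted p = 0.628 with an estimated correlation, and 0.0754 at 5 CPM or more). Of 48 homologous recombination and Fanconi anaemia genes 9 fell, among them the ubiquitin ligase FANCL (log2 -1.39), and the helicase BLM rose (1 rose and 9 fell over the list alone, camera 0.0281, adjusted p = 0.498 with an estimated correlation, 0.0822 in the separate fit and 0.207 at 5 CPM or more). Of 29 lysosome and autophagy genes 7 fell, with the protease CTSD at 608 and 174 CPM (0 rose and 8 fell over the list alone, camera 0.0281, adjusted p = 0.686 with an estimated correlation). The call was lost with fry (0.142), at 5 CPM or more (0.0758) and without scaling (0.0531). It was also lost without PSN1 vehicle replicate 3 and BXPC3 vehicle replicate 4 together (0.0517). In the separate fit 3 rose and 9 fell (camera 0.0434, fry 3.34e-04, and 0.37 with an estimated correlation).

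In MIAPACA2, the question was the same at 150 nM. The immediate early transcription factors FOS and EGR1 fell, FOS from 58.9 ± 18.5 to 6.25 ± 1.74 CPM (log2 -3.24 ± 0.29) and EGR1 from 272 ± 42.3 to 35.2 ± 4.95 CPM (log2 -2.95 ± 0.20, adjusted p 4.97e-09). The MAP kinase phosphatase DUSP1 fell from 61.9 ± 4.01 to 14 ± 5.79 CPM and the peroxide-clearing enzyme CAT from 48.6 ± 15.1 to 9.55 ± 3.50 CPM. MXRA8 (log2 -2.43 ± 0.39), OPLAH (log2 -2.19 ± 0.29) and the unnamed gene AC244197.3 (log2 -2.64 ± 0.45) fell as well. MMP14, a membrane-bound matrix protease, rose from 11.8 ± 5.37 to 95.9 ± 29 CPM (log2 3.03 ± 0.31, adjusted p 2.48e-06), and PLCG1, a phospholipase of receptor signalling, from 135 ± 9.52 to 647 ± 143 CPM. The fucosyltransferase FUT3 rose 10.1-fold, desmin (DES) 8.51-fold, the amine oxidase AOC3 7.83-fold and the kinase WNK4 5.96-fold. In all, 1155 of 22883 genes passed, 622 higher and 533 lower, with 468 and 215 of these at least 2-fold. Without scaling the split was 964 higher and 235 lower, the median shift between the scalings being 0.137 in this line and 0.244 in PSN1. Fitted alone, MIAPACA2 gave 2454 of 18090 genes, 1219 higher and 1235 lower. The split was 1490 and 1546 with the mitochondrial share as covariate and 2644 and 2675 with voom. Of the largest changes 3 lost the joint call without single libraries, with similar log2 values, and passed with MIAPACA2 fitted alone. ASIC4 (3.46 to 17.4 CPM) was lost without MIAPACA2 AM-9747 replicate 2 (log2 2.03, adjusted p 0.0663) or vehicle replicate 2 (2.10, 0.0502), against 2.33 with all libraries and adjusted p 0.00257 alone. The readthrough gene RPL17-C18orf32 (10.6 to 2.42) was lost without AM-9747 replicate 2 (adjusted p 0.084) or 4 or vehicle replicate 1, at log2 -1.94 to -1.86 against -2.13, with adjusted p 0.0135 alone. PSG4 (1.73 to 8.45), which has close paralogs, was lost without any 1 of the 8 libraries (up to 0.105), at log2 2.15 to 2.37 against 2.29, with 3.22e-04 alone.

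In MIAPACA2 8 of the 38 lists were called, and 1 with an estimated correlation. That one was the stress-induced immediate early genes, where FOS, FOSB, IER2, JUN and ZFP36 fell out of 15 and none rose (0 rose and 8 fell over the list alone, median -0.73, camera 5.66e-09, adjusted p = 0.0172 with an estimated correlation). With MIAPACA2 fitted alone the estimated correlation gave a camera adjusted p of 0.061. Of 50 replication and G1/S genes 18 fell and none rose (0 rose and 25 fell over the list alone, median -0.69), with CDC45 at log2 -1.99 and GINS4 going from 218 to 65.6 CPM (camera adjusted p 4.24e-17, and adjusted p = 0.0564 with an estimated correlation). Of the mitosis genes CDC25B, KIF20A and MYBL2 fell (0 rose and 3 fell over the list alone, camera 0.00223, adjusted p = 0.620 with an estimated correlation). The list call was lost with fry (0.254) and at 5 CPM or more (0.116). Of the recombination and Fanconi anaemia list few members passed, 3 of 48 lower and 1 higher (1 rose and 6 fell over the list alone), and the list stood lower at a median of -0.25 (camera 0.0258, adjusted p = 0.392 with an estimated correlation). The list call was lost without scaling (0.2), at 5 CPM or more (0.378), with the mitochondrial share as covariate (0.0549) and without AM-9747 replicate 3 (0.055) or vehicle replicate 2 (0.0842). Integrated stress response genes leaned higher. ASNS, which makes asparagine, rose from 32.8 ± 2.58 to 88.7 ± 6.11 CPM, and ATF3, NUPR1, SLC7A11 and TRIB3 rose too, while DDIT4 and PCK2 fell (9 rose and 3 fell over the list alone, camera 0.00198, adjusted p = 0.392 with an estimated correlation, and 0.0741 with voom).

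The cohesin and synapsis genes REC8, SMC1B, STAG3 and SYCP2 rose in MIAPACA2 out of 17 germ cell genes measured, SYCP2 from 1.36 to 6.39 CPM (9 rose and 1 fell over the list alone, camera 0.00193, adjusted p = 0.0642 with an estimated correlation). The list median was 1.36 over all 17 and 2.23 over the 11 left when 6 members with at most 3 counts in each group were left out. The complement proteases C1R and C1S rose out of 10 fibroblast markers (4 rose and 0 fell over the list alone, camera 0.00349, adjusted p = 0.255 with an estimated correlation, and 0.138 with voom). Of 51 cytosolic ribosomal proteins none passed alone, at a median of -0.25 (0 rose and 0 fell over the list alone, camera 0.00108, adjusted p = 0.678 with an estimated correlation, 0.327 with fry and 0.0629 at 5 CPM or more).

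In PSN1, the question was again the response at 100 nM. On average its treated libraries held fewer mitochondrial counts and more detected genes than its vehicle libraries, with overlapping ranges. Simulated data showed a false share of 71% among PSN1 calls of the joint fit (191 of 269) and 2.78% in a fit of PSN1 alone (1 of 36), so the adjusted p of the separate fit is given beside the genes named in this line, where they were tested in it. INCENP, a scaffold of the chromosomal passenger complex, rose from 15 ± 0.933 to 195 ± 37.4 CPM (log2 3.70 ± 0.30, adjusted p 1.35e-08, separate 1.06e-04). The secreted FSTL1 rose from 0.175 ± 0.211 to 19.2 ± 7.08 CPM (separate 0.00227), the G-protein regulator RGS4 from 0.185 ± 0.218 to 12.3 ± 7.59 CPM (separate 0.00485) and the carboxypeptidase CPA4 from 0.722 ± 0.570 to 37.1 ± 1.45 CPM (separate 6.31e-04). The Wnt antagonist DKK1 rose 10.4-fold (separate 0.0356), the oxidase AOX1 10.2-fold (separate 0.0298) and C11orf86 from 0.703 to 10.5 CPM (separate 0.0121). AC117378.1 passed in the joint fit but not in the separate one or with voom (from 0.689 to 10.3 CPM, separate 0.0563).

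The trypsinogen genes PRSS1 and PRSS2, paralogs that share reads, fell in PSN1 from 93.2 ± 11.5 to 1.43 ± 0.735 CPM and from 380.0 ± 134 to 24.7 ± 5.70 CPM (separate 2.00e-04 and 1.91e-04). The mucosal glycoprotein DMBT1 fell from 157 ± 72.8 to 10.6 ± 4.11 CPM (separate 5.63e-04), the glucosidase PGGHG from 154 ± 63.1 to 8.95 ± 3.56 CPM (separate 8.32e-04), and the hormone ADM2 from 47.4 ± 6.35 to 3.55 ± 1.88 CPM (separate 6.40e-04). ITIH4 (log2 -4.76 ± 0.68), NOX3 (log2 -4.00 ± 0.53) and CAPN8 (log2 -3.93 ± 0.74) also fell (separate 0.00188, 0.00115 and 5.63e-04). The joint fit called 5749 of 22883 genes, 3337 higher and 2412 lower, with 2129 and 1638 at least 2-fold. Fitted alone, PSN1 gave 1955 of 18287 genes, 825 higher and 1130 lower, and 1907 of these were called in both with the same sign. Without scaling the joint split was 5127 higher and 1495 lower, and at 5 CPM or more 2358 and 2425.

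The mitosis genes moved together in PSN1, where 62 of 65 rose and none fell (62 rose and 0 fell over the list alone, 46 rose and 0 fell in the separate fit, adjusted p 7.57e-36). The spindle gene ASPM rose from 7.45 ± 5.20 to 54.4 ± 8.11 CPM (log2 2.85 ± 0.37, separate 0.00659), the centromeric histone CENPA from 1.51 ± 1.90 to 15.4 ± 3.27 CPM (separate 0.0410) and the checkpoint kinase TTK from 5.38 ± 3.58 to 29.9 ± 9.15 CPM (separate 0.00739). Their median log2 fold change was 1.84 (camera 1.17e-46, adjusted p = 0.00403 with an estimated correlation). In the separate fit with an estimated correlation the list was not called (camera adjusted p 0.0929). Of 50 replication and G1/S genes 36 rose and none fell (40 rose and 1 fell over the list alone, 19 rose and 0 fell in the separate fit, adjusted p 5.30e-11, median 1.08). GINS4 went from 1.97 to 4.48 CPM but did not pass in the separate fit (0.155). The list had camera adjusted p 2.37e-16, and adjusted p = 0.0501 with an estimated correlation. The integrated stress response went the other way. Of its genes 20 of 29 fell and ATF3 rose (separate 0.00330; 1 rose and 21 fell over the list alone, 1 rose and 17 fell in the separate fit, adjusted p 1.07e-19). ASNS fell from 315 ± 60 to 52.9 ± 8.08 CPM (separate 2.32e-04) and PSAT1 from 108 ± 45 to 22.3 ± 3.04 CPM (separate 0.00177; median -0.96, camera 9.98e-23, adjusted p = 0.00386 with an estimated correlation). This list too was not called in the separate fit with an estimated correlation (camera adjusted p 0.0929). In the same libraries the mitochondrial share was 33.1% in vehicle and 20% with AM-9747. The joint fit called 19 of 38 lists, 2 with an estimated correlation, and 15 lists higher and 1 lower without scaling.

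Also called higher in PSN1 were 4 lists tied to PRMT5, splicing and ribosome assembly, and the cytosolic ribosomal proteins were called lower. The median log2 fold changes of the 4 lists, in the order below, were 0.74, 0.71, 0.21 and 0.46. All genes tested in PSN1 had a median of 0.0967, and 626 genes matched to the mitosis list on GC content, length and level had 0.362. No matched genes were drawn for these 4 lists, so a wider shift in PSN1 is not excluded for them. Of the 15 genes of the PRMT5 complex and snRNP assembly 7 rose and 2 fell (9 rose and 2 fell over the list alone, 3 rose and 0 fell in the separate fit, adjusted p 0.0417, camera 0.0201, adjusted p = 0.411 with an estimated correlation). The call was lost with the mitochondrial share as covariate (0.0915), at 5 CPM or more (0.0845) and without PSN1 vehicle replicate 2 (0.0519). Of the 27 Sm and snRNP proteins 14 rose (19 rose and 1 fell over the list alone, 3 rose and 0 fell in the separate fit, adjusted p 0.00480, camera 0.00232, adjusted p = 0.507 with an estimated correlation). Of 46 splicing factors 17 rose and 2 fell (19 rose and 3 fell over the list alone, 5 rose and 1 fell in the separate fit, adjusted p 0.0816, camera 0.0379, adjusted p = 0.507 with an estimated correlation). This was lost without AM-9747 replicate 2 (0.0521) or vehicle replicate 3 (0.12), and without vehicle replicate 3 and BXPC3 vehicle replicate 4 together (0.134). It was also lost at 5 CPM or more (0.209), with median-of-ratios scaling (0.0637) and in the separate fit. Of 47 ribosome biogenesis genes 15 rose and 2 fell (21 rose and 2 fell over the list alone, 3 rose and 1 fell in the separate fit, adjusted p 0.00480, camera 0.00232, adjusted p = 0.411 with an estimated correlation). The ribosomal protein genes RPL12, RPL13, RPL18, RPL28 and RPS2 fell (separate 0.0231, 0.0405, 0.0615, 0.0554 and 0.0624; 0 rose and 4 fell over the list alone, 0 rose and 2 fell in the separate fit, adjusted p 0.00465, camera 0.00543, adjusted p = 0.667 with an estimated correlation). The list call was lost with fry (0.269), with voom (0.240), without scaling (0.0835) and without vehicle replicate 1 (0.13).

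DNA repair genes leaned higher in PSN1, with list medians of 0.504 (recombination) and 0.328 (other repair) against 0.0967 over all genes. The recombination list had 15 up and 2 down (17 rose and 2 fell over the list alone, 6 rose and 1 fell in the separate fit, adjusted p 0.0146, camera 0.00232, adjusted p = 0.150 with an estimated correlation). The other repair list of 52 had 18 up and 4 down (19 rose and 4 fell over the list alone, 4 rose and 0 fell in the separate fit, adjusted p 0.0417, camera 0.0165, adjusted p = 0.411 with an estimated correlation), and was lost at 5 CPM or more (0.154). BLM rose at log2 1.52 (separate 0.0218) and FANCL fell at -1.57 (separate 0.0219). Of 14 CDK inhibitors and D cyclins 5 rose and 1, CDK4, fell (separate 0.167; 6 rose and 1 fell over the list alone, 3 rose and 0 fell in the separate fit, adjusted p 0.0885, camera 0.0343, adjusted p = 0.406 with an estimated correlation). The list call was lost without vehicle replicate 3, alone (0.101) or together with BXPC3 vehicle replicate 4 (0.101). It was also lost at 5 CPM or more (0.138), with voom (0.131), with the covariate (0.168) and in the separate fit. Replication-dependent histones had 10 of 28 higher (10 rose and 0 fell over the list alone, 2 rose and 0 fell in the separate fit, adjusted p 0.0186, camera 0.0103, adjusted p = 0.0945 with an estimated correlation), lost without vehicle replicate 1 (0.058) and at 5 CPM or more (0.184).

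The matrix gene SPARC rose in PSN1 from 6.14 ± 4.53 to 62.9 ± 29.7 CPM (separate 0.00738) and the adhesive glycoprotein THBS1 from 4.05 ± 2.71 to 33.5 ± 23.4 CPM (separate 0.0114). Of 28 mesenchymal genes 13 rose and 2 fell (15 rose and 3 fell over the list alone, 9 rose and 2 fell in the separate fit, adjusted p 0.00138, camera 0.00232, adjusted p = 0.0945 with an estimated correlation). The collagens COL1A1 and COL3A1 and the proteoglycans DCN and LUM rose among 10 fibroblast markers (7 rose and 0 fell over the list alone, 1 rose and 0 fell in the separate fit, adjusted p 0.0146, camera 0.0107, adjusted p = 0.248 with an estimated correlation, and 0.158 at 5 CPM or more). Of these COL3A1 passed in the separate fit (0.00522), COL1A1 (0.109) and LUM (0.122) did not, and DCN was not tested there. Of 22 YAP and TEAD targets 12 rose, AMOTL2 from 8.88 to 34.2 CPM (separate 0.00201; 13 rose and 0 fell over the list alone, 5 rose and 0 fell in the separate fit, adjusted p 9.10e-04, camera 7.35e-04, adjusted p = 0.284 with an estimated correlation). Of 46 oxidative phosphorylation genes 9 rose and 1 fell (9 rose and 1 fell over the list alone, 1 rose and 1 fell in the separate fit, adjusted p 0.0475, camera 0.0366, adjusted p = 0.667 with an estimated correlation). The median of this list was 0.451. Its call was lost with the mitochondrial share as covariate (0.792), with fry (0.0504) and at 5 CPM or more (0.158). It was lost as well without AM-9747 replicate 1 (0.0661) or 2 (0.121) and without vehicle replicate 2 (0.172) or 4 (0.114).

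The antigen presentation, NF-kB and MAPK output lists stood lower in PSN1. Of 17 antigen presentation genes 7 fell and TAP1 rose (separate 0.117; 2 rose and 7 fell over the list alone, 0 rose and 3 fell in the separate fit, adjusted p 0.0295, camera 0.0165, adjusted p = 0.406 with an estimated correlation). Of 30 NF-kB and cytokine genes 6 fell, while CCL2 and IL11 rose (separate 0.00173 and 0.00425; 2 rose and 6 fell over the list alone, 2 rose and 3 fell in the separate fit, adjusted p 0.0427, camera 0.0165, adjusted p = 0.406 with an estimated correlation). Of 20 genes of MAPK output 6 fell and 0 rose (0 rose and 6 fell over the list alone, 0 rose and 4 fell in the separate fit, adjusted p 0.0295, camera 0.00891, adjusted p = 0.406 with an estimated correlation), EGR1 at log2 -2.08 (separate 0.00200). Without vehicle replicate 1 the 3 lists were lost, with adjusted p 0.118, 0.118 and 0.0574, and without scaling with 0.115, 0.0727 and 0.085. With voom the first 2 had 0.0578 and 0.0567.

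**Figure D3:**
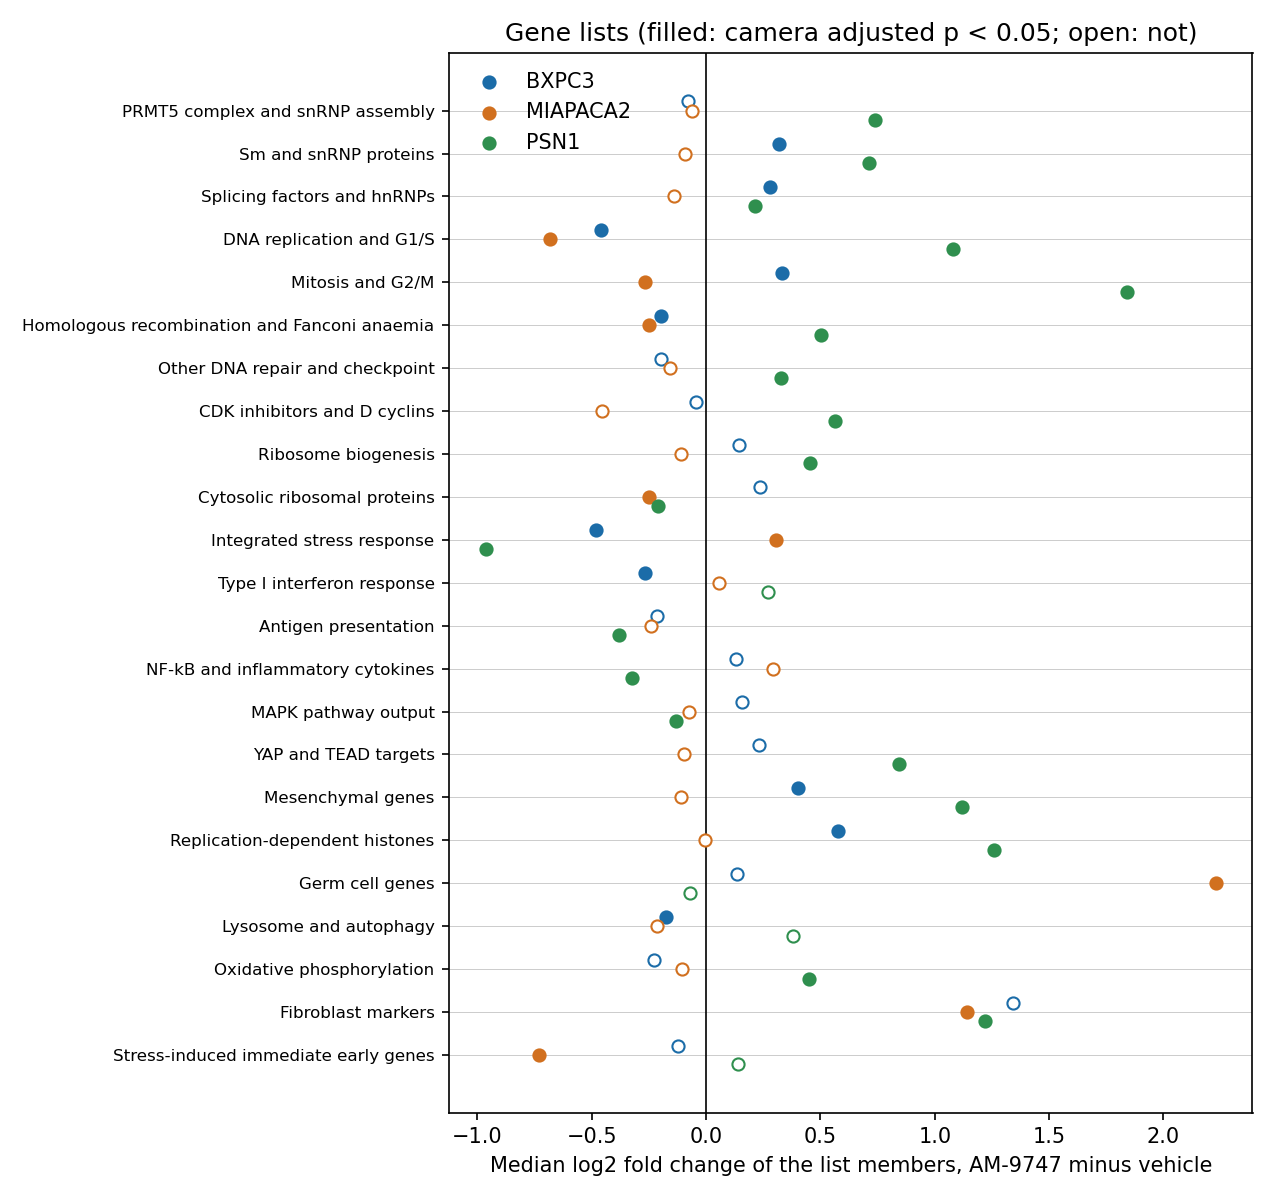
Median log2 fold change (AM-9747 over vehicle) of the members of each gene list called in any line. Members without a count in 1 group are set to a bound of 3 counts and members with at most 3 counts in both groups are left out. Filled points mark a camera adjusted p below 0.05 at the preset correlation. Mitosis and replication genes stand higher in PSN1 and lower in MIAPACA2.

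Across the 3 lines, the question was which genes moved the same way in each. PLCG1 rose in all, by log2 2.31, 2.26 and 1.65 in BXPC3, MIAPACA2 and PSN1. The rRNA methyltransferase NOP2 rose from 97.8 to 404 CPM, from 95.6 to 348 and from 135 to 417. OPLAH, of glutathione turnover, fell from 23.9 to 5.31 CPM, from 26.7 to 5.86 and from 28 to 6.21, and the lysosomal phosphatase ACP2 by log2 -2.69, -1.86 and -1.87. Also higher in each were IVNS1ABP, the microtubule-binding CLASP1, ZNF202, PPIL4, ZNF284, the kinase MINK1, the exchanger SLC4A2 and CBWD3, which has near-identical copies. Also lower in each were CCDC71, PGGHG, the mitochondrial carrier SLC25A10, the complex I assembly factor NDUFAF3, the interferon-induced IFI35, PIGQ, the nucleoside transporter SLC29A2 and LENG9. All 20 passed in the separate fit of PSN1. In all, 280 genes passed the same way in each line, 115 higher where independent lines would give 4.02 and 165 lower where they would give 3.42. Without scaling these were 189 and 70. The lines share no control libraries, but 1 joint fit gave the tests of all lines with a shared estimate of the spread of each gene. Calls are thus not independent between lines, and 4.02 and 3.42 serve only as a reference. Calls lost without single libraries were PPIL4 without BXPC3 AM-9747 replicate 4 (log2 0.96, adjusted p 0.0667) or MIAPACA2 vehicle replicate 3 (1.23, 0.0526), and ZNF284 without BXPC3 AM-9747 replicate 2 or vehicle replicate 1 or 3 (log2 1.02 to 1.05, adjusted p up to 0.0622). LENG9 was lost without MIAPACA2 AM-9747 replicate 1 (log2 -1.14, adjusted p 0.0589) or vehicle replicate 3 (-1.15, 0.0575). SLC29A2 was lost without MIAPACA2 AM-9747 replicate 1, 2 or 4 or vehicle replicate 1 or 3 (log2 -1.36 to -1.20, adjusted p up to 0.0795). All 4 passed in the separate fits of these lines.

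**Figure D4:**
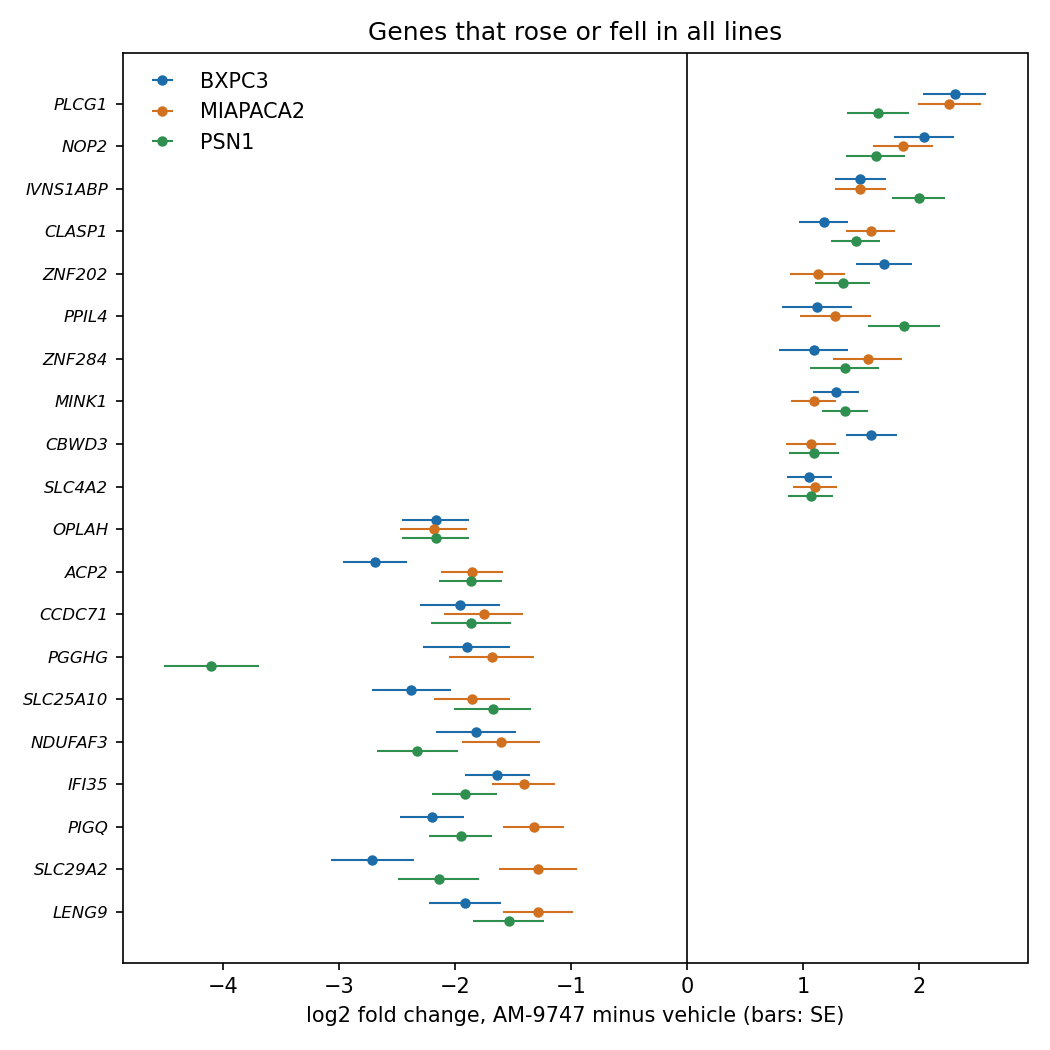
Log2 fold change ± SE (AM-9747 over vehicle, 4 libraries against 4) of the 10 genes that rose and the 10 that fell in each of BXPC3, MIAPACA2 and PSN1, ranked by their smallest change in any line. Only genes with a mean of at least 5 CPM in each line and no overlap of the groups were ranked.

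Over the mean of the lines 5313 genes passed, 2867 higher and 2446 lower, and 4261 and 1575 without scaling. The split was 2213 and 2216 at 5 CPM or more and 1566 and 1601 at adjusted p below 0.01. Simulated data gave a false share of 16% for this test (23 of 144). WDR77 fell in the mean (log2 -0.45 ± 0.10, adjusted p 0.00127, and 0.0583 without scaling). Responses correlated at r 0.239 between BXPC3 and MIAPACA2, 0.171 between BXPC3 and PSN1 and 0.13 between MIAPACA2 and PSN1. Of genes called in both lines of a pair, 94.9% of 508, 91.4% of 1092 and 79.6% of 559 had the same sign.

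The last comparison asked which responses differed between the lines. The stress protein NUPR1 rose in MIAPACA2 from 2.37 ± 0.252 to 8.23 ± 2.05 CPM and fell in PSN1 from 100.2 ± 47.1 to 18.3 ± 6.81 CPM (separate 0.00463; adjusted p of the difference 7.03e-06). KLK10, a secreted protease, fell in BXPC3 from 119 ± 29.8 to 24.7 ± 2.24 CPM and was at traces of 0.0212 and 0.344 CPM in PSN1 (adjusted p 2.62e-06), where the separate fit did not test it or BICDL2. Carry-over from BXPC3 was not excluded for that trace of KLK10, so its PSN1 rise is not taken as a response. BICDL2 fell in BXPC3 from 16.7 ± 3.29 to 3.79 ± 0.618 CPM (log2 -2.06 and adjusted p 0.0524 without AM-9747 replicate 2) and had 0.325 ± 0.261 CPM in treated PSN1 against 0 counts in PSN1 vehicle, where up to 3 counts cannot be excluded. KLHDC7B rose in MIAPACA2 from 0.119 to 0.589 CPM (separate 0.0964) and fell in PSN1 from 18.2 to 1.63 CPM (separate 2.60e-04). The ion channel P2RX1 and the unnamed AC018714.2 fell in PSN1, from 102 to 17.4 CPM and from 27.2 to 5.49 CPM (separate 0.00200 and 0.00174), and rose in MIAPACA2 at traces of 0.314 and 0.149 CPM. The separate fit of MIAPACA2 did not test these genes, so their rises there rest on the joint fit. The calls of those rises were lost on leaving out any 1 of 5 and of 7 of the 8 MIAPACA2 libraries (adjusted p up to 0.101 and 0.162), while the log2 values stayed at 2.49 to 2.84 and 2.76 to 3.35. ASNS, chosen after its values were seen, fell in BXPC3 from 137 to 58.7 CPM and PSN1 and rose in MIAPACA2.

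In total 2760 genes passed for a difference between the lines, 480 between BXPC3 and MIAPACA2, 1909 between BXPC3 and PSN1 and 2377 between MIAPACA2 and PSN1. The difference BXPC3 minus MIAPACA2 was higher in 133 and lower in 347 (72 and 510 without scaling), BXPC3 minus PSN1 in 823 and 1086 (492 and 1835 without scaling) and MIAPACA2 minus PSN1 in 1091 and 1286 (870 and 1203 without scaling). The larger direction of the last 2 pairs depends on the method. For BXPC3 minus PSN1 it was 990 and 988 with median-of-ratios scaling, 1015 and 985 at 5 CPM or more and 1747 and 1729 with DESeq2. For MIAPACA2 minus PSN1 it was 1321 and 1145, 1408 and 947, and 2063 and 1788. The second simulation, with changes in PSN1 alone, gave a false share of 13.3% for the lines together, 12.8% for BXPC3 against PSN1 and 28.6% for MIAPACA2 against PSN1. BXPC3 against MIAPACA2 was not scored in it, and these shares need not hold for the real calls. The mitosis list differed between MIAPACA2 and PSN1 (camera adjusted p 9.55e-57, and adjusted p = 0.00108 with an estimated correlation) and between BXPC3 and PSN1 (5.29e-32 and 0.0185), as did replication and G1/S (8.85e-39 and 0.00108, then 8.82e-29 and 0.0123). The integrated stress response differed between MIAPACA2 and PSN1 (2.02e-30, 0.000659 with an estimated correlation) and between BXPC3 and MIAPACA2 (6.68e-21, 0.00406 with an estimated correlation). Between BXPC3 and MIAPACA2 the splicing factors (1.49e-10, 0.0302 with an estimated correlation) and the immediate early genes (1.29e-05, 0.0302 with an estimated correlation) differed too.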

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

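The tests of the genes rising from near 0 in PSN1 and all tests of other groupings were chosen only after the result was seen, and the other tests were written down before they were run.

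Libraries far from their group were marked by a fixed rule, which marks 1 in 20 groups by chance, and 7 of 74 tests were marked. BXPC3 vehicle replicate 4 stood apart in its mitochondrial share (8.98%), in the share of its 50 most abundant genes (20.8%), and in WDR77 (107 CPM) and MAT2A (209.4 CPM). The top-50 share was marked in MIAPACA2 AM-9747 replicate 3 (18.5%), MTAP in PSN1 AM-9747 replicate 2 (2.463 CPM) and MDM4 in BXPC3 AM-9747 replicate 3 (24.99 CPM).

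Responses that differed between the lines were marked as differences between groups. They are 2760 genes for the lines together, 480 between BXPC3 and MIAPACA2, 1909 between BXPC3 and PSN1 and 2377 between MIAPACA2 and PSN1. MDM4 differed with adjusted p 0.000805, P2RX1 with 0.000579, AC018714.2 with 0.00171, KLK10 with 2.62e-06, KLHDC7B with 8.79e-06, BICDL2 with 0.000534 and NUPR1 with 7.03e-06. Of the 16 largest changes of each line, 13 in BXPC3, 6 in MIAPACA2 and 12 in PSN1 differed between lines, as did 1 of the 20 shared genes (PGGHG) and 40 of the 108 named list members. Of 38 lists, 16 differed between BXPC3 and MIAPACA2, 15 between BXPC3 and PSN1 and 19 between MIAPACA2 and PSN1, against 14 over all pairs with an estimated correlation.

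Mitosis genes stood higher in treated PSN1 libraries, with a median log2 fold change of 1.84, and 3 technical explanations were tested. The mitochondrial share may carry the rise, since it was lower on average in the treated libraries, but with the share as covariate the median was 1.44, which argues against it as the whole cause. Vehicle replicate 3 may carry it, but without that library 60 members were still called higher, and 52 in a separate fit against 46 with it. GC content and gene length may carry it, but 626 genes matched on these and on level had a median of 0.362 (quartiles -0.106 to 0.831), which argues against that too. A higher share of dividing cells among treated PSN1 cells, or unhealthy vehicle cells, could give the same values, and the data cannot tell these apart.

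Integrated stress response genes were lower in BXPC3 and PSN1 and higher in MIAPACA2. Dose may explain the difference, since MIAPACA2 alone had 150 nM, but 0 lines were given more than 1 dose, so dose and line cannot be separated. The mitochondrial share of PSN1 might explain its part, but the median there was -1.17 with the share as covariate, which argues against it. A single library might carry it, but the highest adjusted p over the 24 fits that leave out 1 library was 0.0123, in MIAPACA2, at the preset correlation. With an estimated correlation the list was not called in BXPC3 (0.167) or MIAPACA2 (0.392), nor with voom in MIAPACA2 (0.0741). In PSN1 the estimated correlation gave a call in the joint fit (0.00386) but not in the separate fit (0.0929). Culture conditions such as amino acid supply at day 6 could differ between lines and were not tested.

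For 89 genes with at least 50 CPM in BXPC3 under 2 CPM in PSN1 and under 5 CPM in MIAPACA2, RAB25 and LCP1 among them, the median level in PSN1 was 0.0872, 0, 0 and 0.0233% of the BXPC3 level in the vehicle libraries and 0.342, 0.398, 0.184 and 0.171% in the treated ones. RNA or reads of BXPC3 in the treated PSN1 libraries may explain the rise. Of these genes 39.3% (35 of 89) were below the Poisson limit of a common share, but that limit holds no spread between libraries and takes the profile from other libraries, so carry-over stays open. More low genes being detected in treated PSN1 libraries goes with the pattern: for each gene that lost detection 3.3 gained it, against 1.64 in BXPC3 and 1.15 in MIAPACA2. Depth was not equalised for this ratio. PSN1 vehicle libraries had 33.1% mitochondrial counts against 20% in treated ones, which left fewer counts for other genes and could raise it. Activation of silent genes could raise the same ratio.

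Other groupings of the libraries tell whether chance can be excluded. For genes called, the real grouping had the largest count in BXPC3 (2405, highest other 199; 1 of 35 groupings), MIAPACA2 (1155, highest other 13; 1 of 35) and PSN1 (5749, highest other 5074; 1 of 35). In BXPC3 and MIAPACA2 chance can be excluded at the level of 1 in 35, the lowest that 35 groupings allow. In PSN1 other groupings came close in the joint fit (5074 and 3788 genes), so its joint count does not firmly exclude chance. In PSN1 the other grouping with 5074 genes set vehicle replicate 1 and AM-9747 replicates 1, 2 and 4 (mitochondrial shares from 7.98 to 31.1%) against the rest (26.8 to 43.8%), while the separate fit gave 1955 against a highest other of 0. Separate fits gave 5134 against 2379 in BXPC3 and 2454 against 1587 in MIAPACA2. For lists called, chance cannot be excluded in BXPC3 (10, highest other 13; 3 of 35) or MIAPACA2 (8, highest other 12; 6 of 35). In PSN1 the real grouping had the largest count (19, highest other 18; 1 of 35), but the next was so close that chance is not firmly excluded. Across lines chance can be excluded for the mean response (5313, highest other 2167; 1 of 100). Genes called the same way numbered 280 (highest other 0; 1 of 100). Other groupings within a line called at most 199 genes in BXPC3 and 13 in MIAPACA2, which left few to be shared. That comparison therefore does not test whether a response is shared. The real grouping ranked high but not first for the lines differing (2760, highest other 5225; 2 of 100), BXPC3 and MIAPACA2 (480, highest other 697; 3 of 100), BXPC3 and PSN1 (1909, highest other 3670; 4 of 100) and MIAPACA2 and PSN1 (2377, highest other 3880; 2 of 100). For BXPC3 and PSN1 a further grouping gave 1905 genes, just below the real count. Since other groupings gave more genes than the real one, chance is not excluded for these differences.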

How the results depend on the processing

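Voom, the mitochondrial covariate and leaving out 2 libraries together were chosen only after results were seen, and no other alternative was. Where a value below moved, the cause was not tested.

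List calls depend most on the correlation between members. With an estimated correlation 0 lists were called in BXPC3, 1 in MIAPACA2 and 2 in PSN1, against 10, 8 and 19 as reported and 11, 9 and 27 with fry. The calls in MIAPACA2 and PSN1 were lost when the separate fits used an estimated correlation (camera adjusted p 0.061 in MIAPACA2 and 0.0929 for each list in PSN1). Without the filter 16 were called in BXPC3 and 15 in MIAPACA2, and with at least 5 CPM 12 in PSN1.

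Fitting each line alone gave 5134 genes in BXPC3, 2454 in MIAPACA2 and 1955 in PSN1. DESeq2 gave 2097 in MIAPACA2, 444 the same way in all lines, 4890 for the lines differing, 1136 for BXPC3 against MIAPACA2, 3476 for BXPC3 against PSN1 and 3851 for MIAPACA2 against PSN1. Voom gave 9660 in BXPC3, 5319 in MIAPACA2, 725 the same way, 9253 for the lines differing and 3489, 5383 and 5077 for the pairs. With the mitochondrial covariate there were 4271 in BXPC3, 3036 in MIAPACA2, 668 the same way and 1459 for BXPC3 against MIAPACA2. Leaving out 2 libraries gave 1932 in MIAPACA2 and 754 for BXPC3 against MIAPACA2. Without the filter, 181 genes went the same way, 296 differed between BXPC3 and MIAPACA2 and 1232 between BXPC3 and PSN1. At adjusted p below 0.01, which passes fewer genes by construction, there were 1286, 487 and 2963 in BXPC3, MIAPACA2 and PSN1, 3167 for the mean and 114 the same way. Against a change of 1.2-fold there were 703 in MIAPACA2 and 3293 for the mean.

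The correlation of BXPC3 with MIAPACA2 was 0.313 at 5 CPM or more, 0.307 with voom and 0.124 without the filter, and that of BXPC3 with PSN1 0.274 at 5 CPM or more and 0.108 without the filter. In CPM of library totals CDKN1A was at 110 in BXPC3 vehicle, MDM4 at 48.3 in MIAPACA2 AM-9747 and 58.3 in PSN1 vehicle, MYC at 295 in PSN1 vehicle and WDR77 at 32.9 in MIAPACA2 AM-9747. Directions reversed, none of them passing, for CDKN1A with the covariate (log2 -0.25 in PSN1, -0.0872 in the mean), MDM4 in MIAPACA2 (0.0189 at 5 CPM or more, 0.11 without scaling), PRMT5 in MIAPACA2 (0.0232 and 0.0802) and MYC in PSN1 (0.20 without scaling).

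Leaving out 1 library moved the counts as follows. MIAPACA2 gave 647 (without vehicle replicate 3), 672 and 685 (AM-9747 replicates 2 and 1), 750 (vehicle replicate 2) and up to 1230 (AM-9747 replicate 3), BXPC3 1696 to 2121 and PSN1 4417 to 8274 (without vehicle replicate 1). The mean gave 4756 to 6699, and genes the same way 184 (without MIAPACA2 vehicle replicate 3) to 364. The lines differing gave 1988 to 6121 (without PSN1 vehicle replicate 1), BXPC3 against MIAPACA2 308 and 311 (without BXPC3 AM-9747 replicates 2 and 3), 313 (MIAPACA2 vehicle replicate 3) and up to 792 (PSN1 vehicle replicate 3), BXPC3 against PSN1 1130, 1248 and 1258 (without BXPC3 AM-9747 replicates 3, 4 and 2), 1146, 1202 and 1168 (BXPC3 vehicle replicates 1, 2 and 3), 1230 (PSN1 AM-9747 replicate 1) and up to 5285 (PSN1 vehicle replicate 1), and MIAPACA2 against PSN1 1416 and 1494 (without MIAPACA2 vehicle replicates 2 and 3), 1582 and 1506 (MIAPACA2 AM-9747 replicates 1 and 2) and up to 5396 (PSN1 vehicle replicate 1). Log2 fold changes crossed 0 for MAT2A in PSN1 (-0.90 to 0.17, without vehicle replicate 1), MDM4 in MIAPACA2 (-0.19 to 0.0812, without vehicle replicate 4), MYC in PSN1 (-0.36 to 0.024, without AM-9747 replicate 4) and PRMT5 in MIAPACA2 (-0.29 to 0.10, without vehicle replicate 2).

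A replicate block gave 3363 genes for BXPC3 against PSN1, 3821 for MIAPACA2 against PSN1 and 4423 for the lines differing, and kept 244 of 252 named results. Whether replicate numbers pair treated with vehicle libraries stays open. The own number correlated best for 2, 1 and 2 of 4 in BXPC3, MIAPACA2 and PSN1, and the mean r of equal numbers was 0.314, 0.0942 and 0.18 against -0.127, -0.033 and -0.0591 for other numbers. Of the 252 named results, 252 were kept with median-of-ratios scaling, 248 with DESeq2, 242 without the 2 libraries, 240 without scaling, 239 without the filter, 238 with the covariate and 235 with voom. Of 37 list calls, 37 were kept without the filter and 24 at 5 CPM or more. At this depth MTAP had 5 to 97 counts per library, which limits any statement on it.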

Other observations

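The gene span and GC test of the genes that fell was written down before it was run. No prediction was written for exonic length, for the genes that rose or for the GC correlations in each line.

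Methionine salvage and p53 genes moved singly. MRI1, of the salvage pathway downstream of MTAP, fell in all lines (log2 -0.86, -0.66 and -0.98 in BXPC3, MIAPACA2 and PSN1, and 0.0173 for adjusted p with PSN1 fitted alone), and CBS, of homocysteine removal, fell in PSN1 from 129 ± 35.3 to 24.4 ± 7.73 CPM (alone 0.00200). CBS also went from 1.495 CPM to 0 counts in BXPC3 (adjusted p 5.98e-09, up to 3 counts not excluded) and from 53.6 to 33.6 CPM in MIAPACA2 (adjusted p 0.0829, alone 0.00365). The p53 target TP53I3 fell in all lines (log2 -2.23, -1.49 and -1.30, PSN1 alone 0.0277). CDK4 fell from 144 to 73.9 CPM, from 115 to 54.4 CPM and from 60.7 to 36.6 CPM, but with PSN1 alone its adjusted p was 0.167. IL11 rose in all lines (log2 1.12, 1.47 and 1.45, PSN1 alone 0.00425), and PSMB10 fell in all (PSN1 alone 0.0105). The BH3-only gene PMAIP1 rose and BOK fell in all lines of the joint fit, but with PSN1 alone they did not pass (adjusted p 0.145 and 0.0856). In MIAPACA2 RBM39 rose and HNRNPA1, HNRNPL, PRPF19, SF3B3 and SRSF1 fell among the splicing factors, a list not called there (camera adjusted p 0.0678). These genes were chosen after their values were seen.

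Of the 38 lists, 15 were called in no line by camera at its preset correlation. They are the arginine methyltransferases, methionine salvage and polyamines, p53 targets, the unfolded protein response, TGF-beta targets, epithelial, classical and basal-like genes, the BCL2 family, cholesterol synthesis, hypoxia, nonsense-mediated decay, and leukocyte, endothelial and acinar or endocrine markers. Fry does not set members against other genes, so where many genes passed (25.1% in PSN1) its calls need not be particular to a list. It called 9 of these 15 lists in some line. In PSN1 it called higher nonsense-mediated decay (4.58e-05), leukocyte (8.64e-04), basal-like (0.00232), TGF-beta (0.00263), classical (0.00530), endothelial (0.0117), epithelial (0.0173) and BCL2 family genes (0.0220). In BXPC3 it called epithelial genes lower (0.0115) and nonsense-mediated decay (0.0204) and classical genes (0.0260) higher, and in MIAPACA2 leukocyte (0.0120) and endothelial markers (0.0351) higher and arginine methyltransferases lower (0.0351). None of these calls held in camera with an estimated correlation (adjusted p 0.392 to 0.748). With PSN1 fitted alone, fry kept nonsense-mediated decay (0.0208) and leukocyte markers (0.0198) and lost the other 6 (0.0567 to 0.597). Nearest to the threshold with camera were basal-like genes in PSN1 (camera adjusted p 0.0538, and 0.399 in the separate fit) and epithelial genes in BXPC3 (0.0567, and 0.0460 in the separate fit), where ELF3, KRT19, MUC1 and TJP3 fell. Endothelial markers in BXPC3 had 0.353, and 0.0146 in the separate fit. With an estimated correlation the separate fit gave 0.486 and 0.175 for these 2 lists in BXPC3. Of the 25 basal-like genes 6 had no count in 1 of the PSN1 groups, and carry-over from BXPC3 was not excluded for genes near 0 in PSN1 vehicle. PRMT6 fell in BXPC3, the only methyltransferase of its list to pass in any line of the joint fit.

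The genes that fell in all lines may share gene features. Their median span was 16.7 kb, against 32.5 kb (25.6 to 41.5) for genes matched on level, and their median exonic GC was 58.2% against 48.2% (46 to 50.9). Both values fit a link of the fall with short, GC-rich genes. The genes that rose in all lines had 35 kb and 49.3%, near matched genes, but a median exonic length of 6.34 kb against 5.34 (4.6 to 6.17). The genes that fell had 4.73 kb, within the matched range. Over 10014 genes the Spearman correlation of the response with GC was -0.0909, -0.101 and -0.344 in BXPC3, MIAPACA2 and PSN1. A bias of the libraries and a difference in RNA processing could both give this, and the data do not separate them.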
